A study of Mus musculus with 3 samples.

How the data were processed

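The data are 3 Affymetrix arrays of RNA from sorted Th17 cells, 1 each from spleen, lung and SI-LP, grouped by the tissue that the labels name. Per the labels, cells of each tissue came from SFB-colonised IL-17-eGFP reporter K/BxN mice on a mixed C57BL/6 and NOD background. They were cultured for 4 h with 50 ng/ml PMA and ionomycin (1 mM as the labels give it), which trigger cytokine transcription, and with the secretion blocker GolgiPlug. CD45+ TCRβ+ CD4+ GFP+ cells were then sorted by flow cytometry. The labels give the age as 6 weeks in 1 place and as 5 to 6.5 weeks in another, and the number of mice per array is not given in the sources used here. RNA was labelled with biotin by a whole-transcript kit, per the labels. Each tissue has a single sort and a single array, so effects of sorting purity or of a single preparation cannot be separated from the tissue.

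The authors deposited log2 expression values made by RMA in Affymetrix Expression Console, per the file headers and the submitters' processing notes. RMA corrects background, quantile-normalizes the arrays and summarises each probe set by median polish. The software versions are not given in the sources used here. The 2 deposited tables hold the same values, 1 of them rounded to 1 decimal (largest gap 0.05 on the log2 scale), and the unrounded table was used. Quantile normalization gives the arrays nearly one distribution, so a change shared by most genes cannot be seen. Array medians over named genes were 4.63 (spleen), 4.64 (lung) and 4.59 (SI-LP), and values ran from 1.00 to 13.0. Many probe sets held exactly equal values on 2 or 3 arrays (3350 named genes on all 3), and the cause is not recorded. Among genes past the filter, 19.7% (SI-LP and spleen), 20.8% (SI-LP and lung) and 23.5% (lung and spleen) had equal values on both arrays, which pulls medians of gene lists toward 0.00.

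Of 35556 probe sets, 12 had no value, 19030 had 1 gene symbol, 16486 had none (5858 of these with a NONCODE accession) and 40 had several. Only probe sets with 1 symbol were named, which left 17270 genes. Of their symbols 15393 are current in the mouse RefSeq gene table (GRCm38.p6) and 985 matched through an older symbol, and the text gives the symbol of the array with the current one beside it where it names a change. For the 912 genes with more than 1 probe set, the one with the highest mean was used. Probe sets without a symbol were not analysed here, apart from those in the immunoglobulin loci, so 94 of the 434 genes on the lists have no value below, among them Il22, Ccl4 and Il7r of the pathogenic signature, Maf and Ikzf3 of the non-pathogenic one, Foxp3, Gata3, Il4 and Il21.

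For each of the 3 pairs the log2 values were subtracted gene by gene. A gene was kept if its value on the brighter array of the pair lay above that array's median over named genes. Where the value on the dimmer array lay below its median, as for many of the largest differences below, the fold rests on a dim value and is not exact. With 1 array per tissue no test was possible, so genes were counted by size, at least 2-fold in each direction. The only measure of technical spread was the gap between probe sets of the same gene on the same pair of arrays. The SD per probe set was 0.18 for SI-LP over spleen (372 genes), 0.19 for SI-LP over lung (377 genes) and 0.19 for lung over spleen (370 genes), 95% of gaps were under 0.54, 0.54 and 0.55, and 3 genes in each pair had a gap of 1 or more. This spread leaves out sorting, RNA preparation, hybridisation and the difference between mice. The brightest genes had a median log2 difference of 0.19 for SI-LP over spleen (1785 genes), 0.20 for SI-LP over lung (1782 genes) and 0.00 for lung over spleen (1779 genes), so list percentiles were taken among lists of like brightness.

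The following choices were made before the data were examined: the comparisons, 39 gene lists, the filter, the size limit, the alternatives and the rule for named genes. The signature lists are the published core sets of 16 pathogenic and 7 non-pathogenic Th17 genes plus Cd5l, written from general knowledge and not copied from the deposited files, and the other lists cover T cell programs, activation, metabolism and 14 kinds of other cells that a sort could hold. For each list with at least 3 measured members, the median difference and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, were computed. The percentile describes these arrays and is not a test, and genes of a list vary together. Outside the range means beyond the 2.5 and 97.5 percentiles of the random lists. Named genes are the 12 with the highest and the 12 with the lowest difference in each comparison (leaving out predicted genes, small RNA genes, pseudogenes by name and antigen receptor segments), all measured signature genes, and up to 4 members of each other list. A few genes that this rule selects are not reported here by name, but they count in all totals and medians. Genes named beyond that rule in lists of a few genes or in the closing section were chosen after their values were seen.

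The calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 (lowess, span 0.3). They were tested on simulated lists and genes, with the real differences shuffled across the genes past the filter. Shuffling removes the brightness trend and the joint variation of a list's genes, so the rates below need not hold for the real lists. Of 400 unchanged lists, 6.75% lay outside the range for SI-LP over spleen (8927 genes), 4.00% for SI-LP over lung (8914 genes) and 5.50% for lung over spleen (8896 genes). Lists of 12 genes raised by 0.3 were found above the range in 97.0%, 100.0% and 100.0% of 200 draws, and 98.0%, 99.5% and 99.0% of 200 genes raised 4-fold were counted as higher. Alternatives were the mean over probe sets, no filter, a filter at the 75th percentile, arrays centred on their medians, quantile normalization over named genes, removal of an intensity-dependent lowess trend, the rounded table, size limits of 1.5-fold and 3-fold, unmatched random lists, list means in place of medians, and signature lists with single genes left out or added.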

Results

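Gene expression was measured in Th17 cells, the CD4 T cells that make interleukin 17, sorted from the spleen, the lung and the small intestinal lamina propria (SI-LP) of K/BxN mice that carried an IL-17-eGFP reporter. K/BxN mice develop spontaneous autoimmune arthritis, and the mice were colonised with segmented filamentous bacteria (SFB), gut commensals known to induce Th17 cells in the small intestine. There were 3 arrays, 1 per tissue, so no replicates: every difference below is between 2 single arrays, without a p-value or a standard error. The words higher and lower in counts mean a difference of at least 2-fold (1 on the log2 scale). The number of arrays limits the precision of all values. On 9051 of the 17270 named genes (52.4%) at least 2 arrays held exactly the same value. Across these genes the arrays correlated with r of 0.979 (SI-LP and spleen), 0.985 (SI-LP and lung) and 0.986 (lung and spleen). Genes are not independent replicates.

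The main question of the design was how SI-LP Th17 cells differ from those of spleen and of lung in the genes of the pathogenic and non-pathogenic Th17 signatures. Against spleen, SI-LP had more transcript of Cxcl3, a neutrophil-attracting chemokine (4.64-fold), of Il3, a hematopoietic growth factor (3.59-fold), and of Icos, a costimulatory receptor (2.78-fold). In the same pathogenic signature Ccl3 was 7.10-fold lower, Ccl5 6.28-fold lower and the galectin gene Lgals3 2.02-fold lower in SI-LP. The other 7 measured members lay between these limits, with log2 differences of 0.92 for Stat4, 0.59 for Csf2, 0.34 for Lag3, 0.31 for Casp1, -0.37 for Gzmb, -0.45 for Tbx21 and -0.62 for Lrmp. The pathogenic signature thus had 13 measured members of 16, 3 of them higher and 3 lower, and a median of 0.31, at percentile 96.4 of 10000 random lists matched on expression. The middle 95% of those lists, called the random range here, ran from -0.04 to 0.33. The mean of the list was -0.02, since the largest differences were the negative ones of Ccl3 and Ccl5. Of the non-pathogenic signature, 4 of the 6 named members were bright enough: Il1rn, the interleukin 1 receptor antagonist, was 6.78-fold lower in SI-LP, and the log2 differences were 0.80 for Il10, -0.16 for Ahr and -0.21 for Il6st. Its median was -0.18, at percentile 4.32. Il9 and Cd5l were dim on both arrays. The pathogenic median lay 0.49 above the non-pathogenic one, at percentile 98.3 of 10000 pairs of random lists. On the same 2 arrays the neutrophil list had a median of -3.09, and Il1rn and Ccl3, genes that myeloid cells also express, differed in the same direction.

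Against lung, the same 2 genes led the pathogenic signature: Cxcl3 was 3.99-fold and Il3 2.84-fold higher in SI-LP, and Stat4, a transcription factor of interleukin 12 and 23 signalling, was 2.25-fold higher. Ccl3 was 3.07-fold lower, Lgals3 2.33-fold lower and Ccl5 2.28-fold lower. The log2 differences of the other 7 members were 0.97 for Icos, 0.60 for Casp1, 0.56 for Csf2, 0.27 for Lag3, -0.14 for Lrmp, -0.36 for Gzmb and -0.42 for Tbx21. The list's median was 0.27, at percentile 91.4 of the random lists. It was 0.56 under a stricter filter on dim genes, and the mean was 0.16. With the brightness trend between the arrays removed by lowess, the pathogenic median lay above the random range in both comparisons (0.26 against spleen and 0.25 against lung), a range computed after the data were seen. In the non-pathogenic signature Il1rn was 2.41-fold lower and Il10, an anti-inflammatory cytokine, 2.26-fold lower in SI-LP, while the log2 differences were 0.25 for Ahr and -0.19 for Il6st. Its median of -0.68 lay below the random range (-0.20 to 0.51) and moved to -0.09 when the dim members Il9 and Cd5l were counted. The gap between the medians was 0.95, at percentile 99.97. It was 0.36 with dim genes counted, and 0.45 without Il1rn, an alternative chosen after the data were seen. On this pair of arrays the neutrophil list had a median of -0.48 (-0.20 with dim genes counted). The macrophage and monocyte list had a median of -0.48 as well, with Lyz2, Cd14 and Cd68 (-1.19) lower in SI-LP, and Il1rn, Ccl3 and Lgals3, which myeloid cells also express, differed in the same direction.

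**Figure D1:**
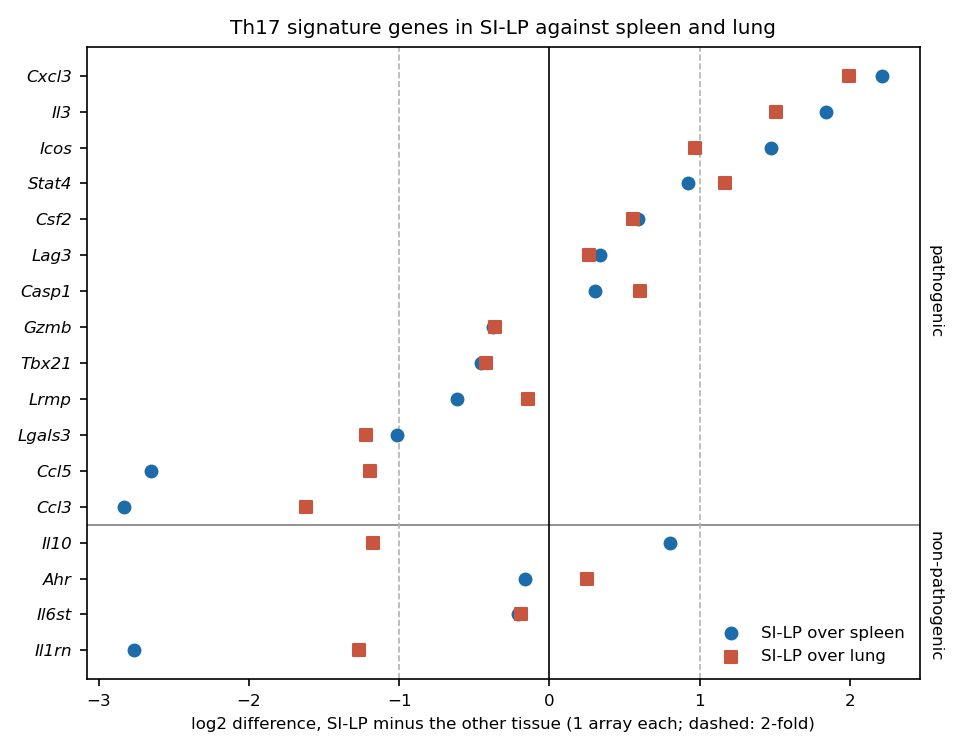
Log2 difference of each measured signature gene past the filter on dim genes, SI-LP minus spleen (circles) and SI-LP minus lung (squares), with 1 array per tissue and dashed lines at a 2-fold difference. Cxcl3 and Il3 lie beyond 2-fold on the positive side and Ccl3, Ccl5, Lgals3 and Il1rn on the negative side of both comparisons, while Il10 is at 0.80 against spleen and -1.17 against lung.

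By the mouse RefSeq annotation of GRCm38.p6, Cxcl3 lies on chromosome 5 from 90786101 to 90788093 (probe set 10523138) and Il3 on chromosome 11 from 54265085 to 54267279 (probe set 10385918). Ccl5 lies on chromosome 11 from 83525778 to 83530518 (probe set 10389207) and Ccl3 on the same chromosome from 83647843 to 83649378 (probe set 10389231). Il1rn lies on chromosome 2 from 24336860 to 24351491 (probe set 10469816) and Il10 on chromosome 1 from 131019845 to 131024970 (probe set 10349603). The leading SI-LP genes Tff2 (chromosome 17, 31141062 to 31144282, probe set 10449661) and Muc6 (chromosome 7, 141633459 to 141655393, probe set 10569227) and the T cell genes Ptpn4 (chromosome 1, 119652467 to 119837585, probe set 10357191) and Ccr9 (chromosome 9, 123767211 to 123783457, probe set 10590620) are protein-coding genes too. A probe set value summarises probes over the whole transcript and gives no exon.

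Over all genes past the filter, the largest difference in favour of SI-LP against spleen was that of Tff2, a trefoil peptide of mucus. It was 23.0-fold higher in SI-LP than in spleen, the gastric-type mucin Muc6 11.7-fold and the gastrokine Gkn3 9.47-fold. In spleen Tff2 (4.09), Muc6 (4.46) and Gkn3 (4.18) lay below the array's median of 4.63, so these folds are not exact. The phosphatase gene Ptpn4 was 7.91-fold higher, the gut homing receptor Ccr9 6.29-fold, and Lztfl1 4.54-fold. The others among the 12 leading genes were Cxcl3, the drug efflux pump Abcb1b (log2 difference 2.40), the defensin Defa23 (2.28), Glyat (2.16), Sgtb (2.12) and Rrad (2.12). The largest differences in the other direction were Lcn2 (35.6-fold lower in SI-LP), Irg1, now named Acod1 (34.9-fold), and S100a9 (24.6-fold). After them came Clec4d (-4.62), Niacr1, now Hcar2 (-4.49), Ngp (-4.37), Thbs1 (-4.06), Il1f9 (-4.03), Sgms2 (-3.75), Slc7a11 (-3.72), Il1b (-3.60) and S100a8 (-3.58). In SI-LP, Lcn2 (3.52), Irg1 (4.55), Clec4d (4.12), Ngp (2.65), Il1f9, Slc7a11 and S100a8 lay below the array's median of 4.59. Their folds and ranks rest on dim values and are not exact. In all, 129 genes were higher and 185 lower in SI-LP among the 8927 genes past the filter on dim genes (3.52%). Defa23, and Abcb1b with its copy Abcb1a, belong to families of near-identical genes, and their probes may share signal.

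Among the gene lists fixed for T cell functions, the Th17 lineage list stood highest against spleen, with a median of 0.59 over 13 measured members of 16. Il1r1 (1.14) and Ccl20 (1.07) were higher and none was lower, with Batf at -0.51. Il17a and Il17f, the cytokines of the reporter locus and its neighbour, differed by 0.60 and 0.67. The T cell cytokine list had a median of 0.44 (20 members, 2 higher and 3 lower), with Il3 and the epidermal growth factor family member Areg (1.81) at the top and Osm (-2.37) and Csf1 (-2.71) at the bottom. Both medians lay above the random range, and they were 0.38 and 0.23 after the lowess correction. The Th1 list had a median of -0.45, 3 of 11 members being lower, Ccl5 and the cytotoxic granule gene Nkg7 (-1.67) most, with Stat4 and Il12rb2 (0.45) at the other end. The Th2 list had a median of -1.01 with 4 of 7 lower, among them Ccr8 (-2.13) and Il13 (-1.24), but Areg higher. The list of lymphoid recirculation genes had a median of -0.53: the chemokine receptor Ccr7 (-1.26) was lower, Satb1 was at 0.61 and Bach2 at 0.36. Chemokine genes had a median of -1.91, with Cxcl3 and Ccl20 higher and 5 of 8 lower, Ccl3 and Ccl5 most, and of -0.98 with dim genes counted. The medians of these 4 lists lay below the random range.

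Smaller shifts below the random range against spleen were those of cytotoxic genes (-0.37, Nkg7 and Klrg1 lower, Fasl at 0.45 and Gzma at -0.12), glycolysis genes (-0.18, none of 11 beyond 2-fold, from Gapdh at 0.12 to Hk2 at -0.53), and interferon-stimulated genes (-0.18, from Oasl1 at 0.23 to Rsad2 at -0.81). Immediate early and activation genes had a median of -0.10, Fosl2 (1.26) being higher and Dusp1 (-1.14) lower. Inflammatory homing receptors had a median of -0.11, Cxcr6 being higher and Ccr4 (-1.04) and Ccr8 lower, and 0.01 under a stricter filter on dim genes. Within the random range lay the lists of inhibitory receptors (0.34, Havcr2 at 1.40, Ctla4 at 1.33, Btla and Entpd1 lower, the latter at -1.55, and a median of 0.30 above the range after the lowess correction), other IL-23-linked genes (0.27, Gpr65 at 1.60, Il1r1 higher, Ccl9 at -1.56), heat shock genes (0.21, Bag3 at 0.51, Hspa8 at -0.29) and tissue residency genes (0.15, Cxcr6 and Rgs2 higher, the latter at 1.47, Litaf at -0.92, Dusp1 at -1.14). The same held for xenobiotic response genes (0.12, Abcb1b and Abcb1a higher), cholesterol synthesis genes (0.09, Sc5d at 0.49, Srebf2 at -0.17), cell cycle genes (0.00, Pcna at 0.77, Mki67 at -1.28) and pan T cell genes (-0.03, Cd5 at -0.61). It held for follicular helper genes (-0.04, Icos higher, Slamf6 at -1.03), regulatory T cell genes (-0.04, Ctla4 at 1.33, Tnfrsf18 at -1.24) and gut homing genes (-0.14, Ccr9 higher and the other 4 between the limits, Itgae at -0.50). The Trbv list had 1 named segment, Trbv1, at -0.14.

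**Figure D2:**
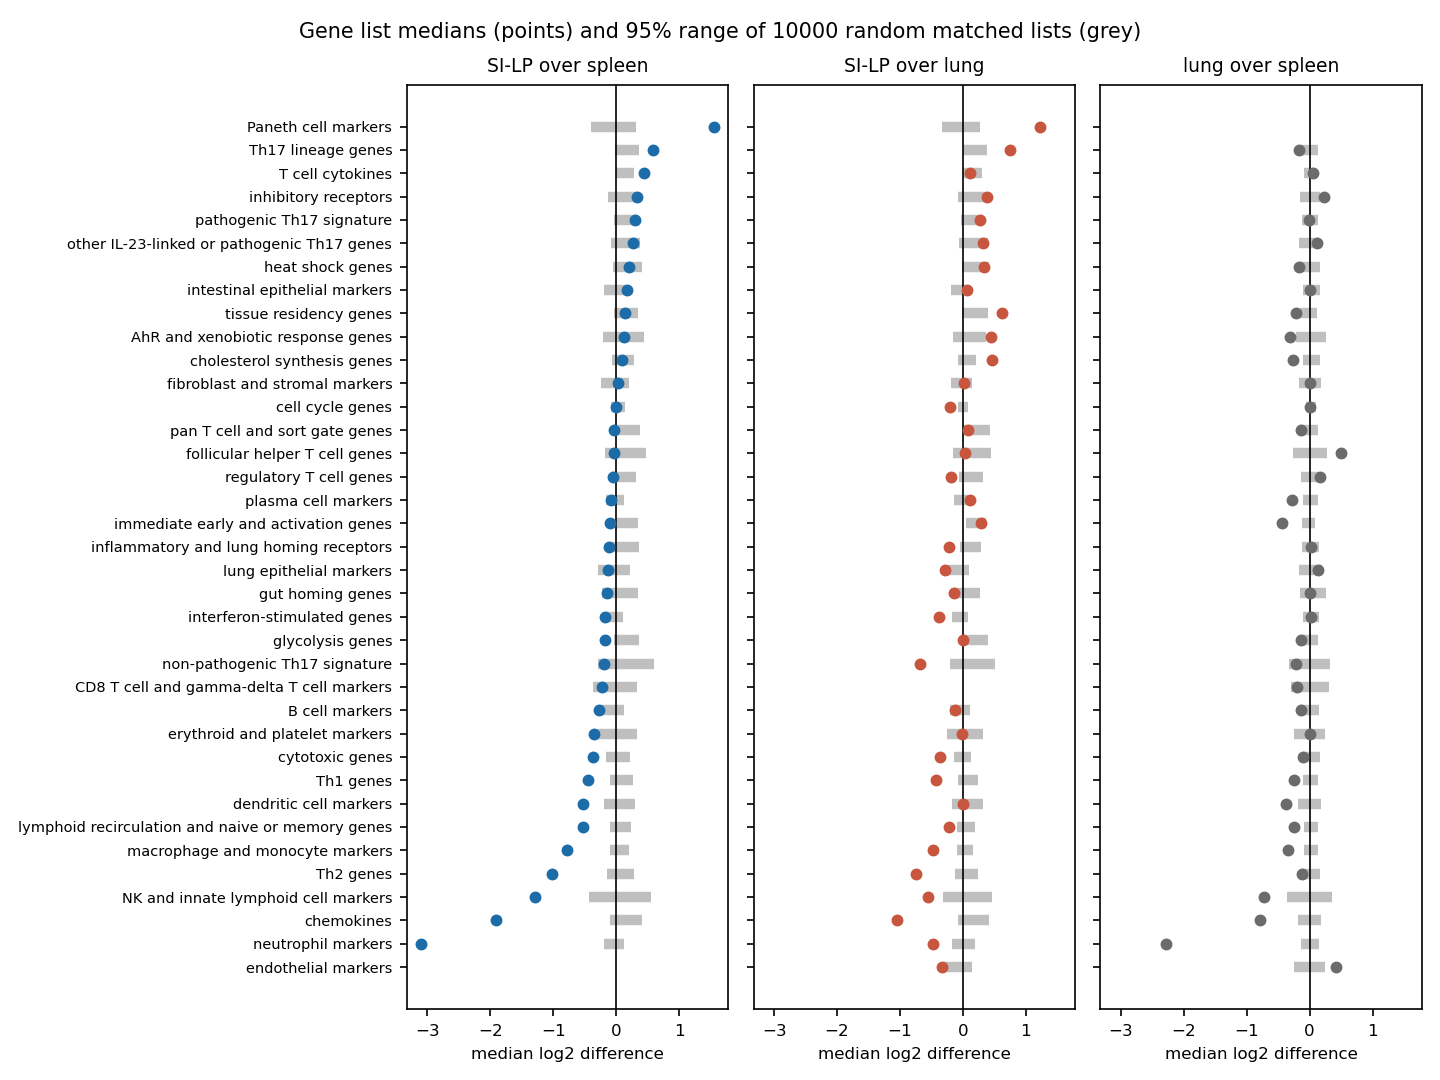
Median log2 difference of each gene list with at least 3 measured members (points) in the 3 comparisons, beside the middle 95% of the medians of 10000 random lists of the same size and expression (grey bars). The Th17 lineage median is 0.59 against spleen and 0.74 against lung, and the neutrophil median is -3.09 for SI-LP over spleen and -2.29 for lung over spleen.

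Markers of cells outside the sort gate differed as well between SI-LP and spleen. The neutrophil list had a median of -3.09, 5 of 7 measured members being lower in SI-LP, S100a9 (-4.62) and Ngp (-4.37) most, with Mmp9 at -0.19 and Camp at -0.91, and the median was -1.41 with dim genes counted. Macrophage and monocyte markers had a median of -0.78, Cd14 (-2.48) and Itgam (-1.78) being lower, while C1qa was at 0.56 and Mrc1 at 0.38. The medians were -1.29 for NK and innate lymphoid markers (Tyrobp -1.91, Fcer1g -1.29, Kit 2.01), -0.53 for dendritic cell markers (Itgax -1.12), -0.36 for erythroid and platelet markers (Hbb-bt -2.21) and -0.27 for B cell markers (Ebf1 -0.90), all below the random range. Paneth cell markers had a median of 1.55 over 3 members, Defa24 (2.02) and Lyz1 (1.55) being higher and Ang4 at 0.52, and of 0.52 with dim genes counted. Intestinal epithelial markers had a median of 0.18 over 5 bright members, also above the range, with Krt8 at 0.26 and Olfm4 at -1.18, and a mean of -0.11. Within the range lay plasma cell markers (-0.08, though Igj, now Jchain, was at 1.77), lung epithelial markers (-0.13, Napsa at -0.97), CD8 and gamma-delta T cell markers (-0.22, Cd8a at -0.41) and fibroblast markers (0.03, Dcn at 0.99). Mast cell and eosinophil markers had none of 8 members bright on any pair of arrays, and the endothelial list had 1 against spleen.

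Against lung, the leading SI-LP genes were again Tff2 (23.5-fold higher), Gkn3 (12.7-fold) and Muc6 (10.7-fold), with the immunoglobulin joining chain gene Igj (13.2-fold) and the defensins Defa24 (9.98-fold) and Defa23 (7.51-fold). Of T cell or receptor genes, Ramp3 (6.10-fold), Ptpn4 (6.00-fold), Abcb1a (5.73-fold) and the stem cell factor receptor Kit (4.49-fold) followed, with Glyat at 4.68-fold. Kit is also on the list of NK and innate lymphoid markers. The largest difference overall was Scgb1a1, the secretoglobin of airway club cells, 59.7-fold lower in SI-LP. Chi3l3, now Chil3, a macrophage chitinase-like protein, was 23.5-fold lower. In SI-LP Scgb1a1 (2.44) and Chi3l3 (2.90) lay below the array's median of 4.59, so their folds and ranks are not exact. Hemoglobin genes followed (Hba-a2 at -3.44, Hbb-bt at -2.94, Hbb-bs at -2.93), with the eosinophil-associated ribonucleases Ear1 (-3.33), Ear12 (-3.15) and Ear2 (-3.11). Thbs1 was 7.59-fold lower, the chemokine receptor Ccr8 6.26-fold, Klrg1, a receptor of terminally differentiated lymphocytes, 6.04-fold, and the activin subunit Inhba 5.84-fold. In all, 104 genes were higher and 113 lower in SI-LP among 8914 (2.43%). The Ear, Hbb and Defa genes are near-identical copies, and the values of single members are uncertain.

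The Th17 lineage list had a median of 0.74 against lung, above the random range of 0.00 to 0.38, with Il1r1 (1.03) and Il23r (1.02) higher and Batf at -0.24. Il17a and Il17f differed by 0.53 and 0.83. Tissue residency genes had a median of 0.62 (Rgs2 1.20, Nr4a2 0.92, Litaf -0.46, Itgae -0.71, and a median of 0.33 after the lowess correction), cholesterol synthesis genes of 0.47 with none of 12 beyond 2-fold (Idi1 0.79, Sc5d 0.74, Fdft1 0.00, and a median of 0.29 after quantile normalization), xenobiotic response genes of 0.44 (Abcb1a and Abcb1b higher) and inhibitory receptors of 0.38 (Ctla4 1.03, Havcr2 0.69, Pdcd1 -0.99, Entpd1 -1.17). These 4 lay above the random range. Some residency genes, such as Nr4a2 and Dusp1, are also on the immediate early list, so residency and the response to the stimulation were not told apart. Below it lay chemokines (-1.05, Cxcl3 higher and Ccl3, Cxcl2 at -1.26, Ccl5 and Xcl1 lower), Th2 genes (-0.75, Ccr8 and Il5 at -1.35 lower, Areg at 2.05 higher) and Th1 genes (-0.42, Nkg7 at -1.41 and Ccl5 lower, Stat4 higher). So did interferon-stimulated genes (-0.38, Rsad2 -0.55), cytotoxic genes (-0.36, Klrg1 and Nkg7 lower, Gzma at 1.15 higher), recirculation genes (-0.22, Cd27 at -1.56 and Ccr7 lower, Satb1 at 1.30 higher), inflammatory homing receptors (-0.22, Ccr8 lower), cell cycle genes (-0.20, Mki67 -0.60, Pcna 0.28) and regulatory T cell genes (-0.19, Il10 lower, Ctla4 higher). Within the range lay heat shock genes (0.34, Hspa1a 0.89, Dnajb1 0.89), other IL-23-linked genes (0.32, Cxcr3 -0.77), immediate early genes (0.29, Fosl2 1.11), T cell cytokines (0.11, Areg and Il3 higher, Il5 and Il10 lower), pan T cell genes (0.08, Cd4 0.82, Lat -0.64), follicular helper genes (0.03, Pdcd1 -0.99), glycolysis genes (0.00, Pdk1 -0.49, and a median of -0.245 below the range after the lowess correction) and gut homing genes (-0.14, Ccr9 1.98). Trbv1 was at -0.19.

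Of other cell types against lung, macrophage markers had a median of -0.48 (Cd14 and Lyz2 both at -1.59, but C1qa at 0.59 and C1qc at 0.40), neutrophil markers of -0.48 over 4 bright members (S100a9 -1.54, Retnlg -0.80, and -0.20 with dim genes counted) and NK and innate lymphoid markers of -0.56 (Tyrobp -0.82, Kit 2.17, and a mean of 0.26). Lung epithelial markers had a median of -0.28 (Scgb1a1 lower and Sftpc at -1.96, with a median of -1.96 under a stricter filter on dim genes and a mean of -1.41) and endothelial markers of -0.32 (Cdh5 -1.37), all 5 below the random range. Paneth cell markers (1.22, Defa24 at 3.32, and 0.00 with dim genes counted) and plasma cell markers (0.12, Igj at 3.72, Pou2af1 at -0.70) lay above it. B cell markers (-0.12), dendritic cell markers (0.00, H2-Aa 0.68, Itgax -0.74), erythroid and platelet markers (-0.01, Hbb-bt -2.94), fibroblast markers (0.03, Dcn 0.16) and intestinal epithelial markers (0.07, Krt8 0.31) lay within it. The CD8 and gamma-delta T cell list had 2 bright members, Cd8a at -0.21 and Sox13 at -0.27.

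**Figure D3:**
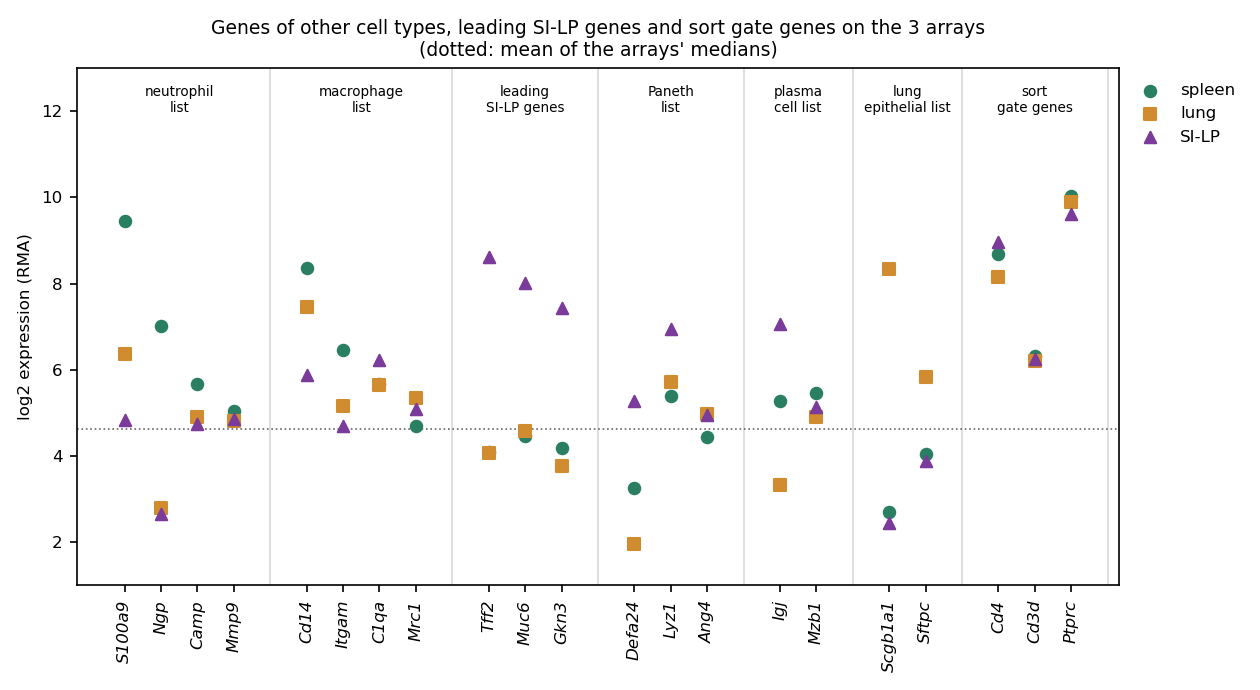
Log2 expression on the spleen, lung and SI-LP arrays (1 each) of genes from the lists of other cell types, of the 3 leading SI-LP genes and of sort gate genes. S100a9 and Ngp are highest on the spleen array, Scgb1a1 on the lung array, and Tff2, Muc6 and Gkn3 on the SI-LP array, where Tff2 is at 8.61 against 4.09 in spleen and 4.06 in lung.

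Lung and spleen differed least, with 45 genes higher and 127 lower in lung among 8896 (1.93%). Scgb1a1 was 49.9-fold higher in lung, the hypoxia-inducible factor Epas1 4.80-fold, the cytokines Il5 4.11-fold and Il10 3.94-fold, and the surfactant protein gene Sftpc 3.44-fold. Ear1 (2.80), Ear12 (2.32), Ear2 (2.16), Chi3l3 (2.13), Gpr116, now Adgrf5 (2.10), Ctla2a (1.83) and Atp6v0d2 (1.75) completed the 12. Lower in lung were Ngp (18.8-fold), Lcn2 (15.7-fold), Niacr1 (10.1-fold) and the cytokine Il6 (9.74-fold). S100a8 (-3.21), Il1f9 (-3.09), S100a9 (-3.08), Irg1 (-3.03), Il1b (-2.56), Mrgpra2b (-2.45), Ccrl2 (-2.43) and Slfn4 (-2.29) followed. The pathogenic signature had a median of -0.01, with Ccl5 (-1.46) and Ccl3 (-1.21) lower and Icos at 0.50. The non-pathogenic one had a median of -0.22, with Il10 higher (1.98), Il1rn lower (-1.49), Ahr at -0.41 and Il6st at -0.02. The gap of 0.21 was at percentile 91.4.

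Between lung and spleen, the follicular helper list (0.50, Pdcd1 0.95, Btla -1.03), endothelial markers (0.42, Cdh5 1.57), inhibitory receptors (0.23, Pdcd1 0.95, Btla -1.03) and regulatory T cell genes (0.17, Il10 and Capg higher, the latter by 1.11) lay above the random range. The follicular helper median was -0.01 with dim genes counted. Below the range lay neutrophil markers (-2.29, 5 of 7 lower, and -1.15 with dim genes counted), chemokines (-0.78, Ccl5 and Xcl1 at -1.41 lower, Ccl1 at 1.12 higher, and -0.28 with dim genes counted), NK and innate lymphoid markers (-0.73, Tyrobp -1.09), immediate early genes (-0.44, Nfkbid -1.19, Egr2 0.40), dendritic cell markers (-0.38, H2-Aa -1.33), macrophage markers (-0.35, Itgam -1.30, Lyz2 0.82) and xenobiotic response genes (-0.32, Abcb1b 0.90, Abcb1a -0.55). So did plasma cell markers (-0.27, Igj -1.94), cholesterol synthesis genes (-0.27, Hmgcs1 -0.48), recirculation genes (-0.26, Tcf7 -1.24, Cd27 0.82), Th1 genes (-0.25, Ccl5 -1.46, Cxcr3 0.89), tissue residency genes (-0.22, Nr4a2 -0.78, Cxcr6 0.74, and 0.02 with dim genes counted), Th17 lineage genes (-0.16, none of 13 beyond 2-fold, Tmem176b -0.34, Ccl20 0.33, and -0.09 within the range after the lowess correction) and cytotoxic genes (-0.10, Gzma -1.26, Klrg1 1.21). Within the range lay lung epithelial markers (0.14), other IL-23-linked genes (0.11, Gpr65 1.28), T cell cytokines (0.05, Il5 and Il10 higher, Osm -1.52, Csf1 -2.21), interferon-stimulated genes (0.03), inflammatory homing receptors (0.03, Cxcr3 0.89), erythroid markers (0.00), gut homing genes (0.00, Ccr9 0.68), cell cycle genes (0.00), fibroblast markers (0.00) and intestinal epithelial markers (0.00, Olfm4 -1.25). Th2 genes (-0.12, Il5 2.04), pan T cell genes (-0.13), B cell markers (-0.14), glycolysis genes (-0.14), heat shock genes (-0.16, Hspa1a -1.08) and CD8 and gamma-delta markers (-0.20) also lay within it. The Paneth list had 2 bright members, and Trbv1 was at 0.05. Of the 36 lists with a median in each comparison, 19 lay outside the range for SI-LP over spleen, 22 for SI-LP over lung and 18 for lung over spleen, where 1.80 would lie outside by chance. The lists share genes and their genes vary together.

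Genes that set SI-LP apart from both other tissues numbered 59 higher and 53 lower of 8780. The 59 held Tff2, Muc6, Gkn3, Ptpn4, Ccr9, Kit, Cxcl3, Il3, Areg, Il1r1 and Ctla4, and the 53 held Ccl3, Ccl5, Ccr8, Ccr7, Klrg1, Nkg7, Il10ra (-1.43 and -1.28), Il10rb (-1.31 and -1.01), Cd80 (-1.73 and -1.69), Irf8 (-1.55 and -2.22), Lcn2 and Thbs1. The 53 also held Cd14, Cd68, S100a9 and Hbb-bt of the lists of other cell types, and the hemoglobin genes Hba-a2 and Hbb-bs. Those lists do not hold every gene of other cells. The macrophage gene Chi3l3 and Clec4d, Il1b and Irg1, which are on none of them, were also among the 53. The 59 also held Defa24, Lyz1 and Igj of those lists. Kit, named above among the 59, is on the list of NK and innate lymphoid markers too. Which cells gave the signal of a gene in either set was not tested. Lists drawn independently would share 1.53 and 1.97 genes, but both comparisons use the same SI-LP array, so part of the excess can come from that array alone. With spleen in the shared place the counts were 95 and 12, and with lung 24 and 20. The 2 sets of differences correlated across genes with r of 0.70, against 0.51 in simulated unchanged genes on arrays of equal error. With spleen or lung shared, r was 0.61 and 0.27. The covariance was 0.11 for SI-LP, 0.09 for spleen and 0.03 for lung as the shared array. These values were unequal, unlike in the simulation, so the gap between 0.70 and 0.51 does not measure a difference of SI-LP from both tissues.

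**Figure D4:**
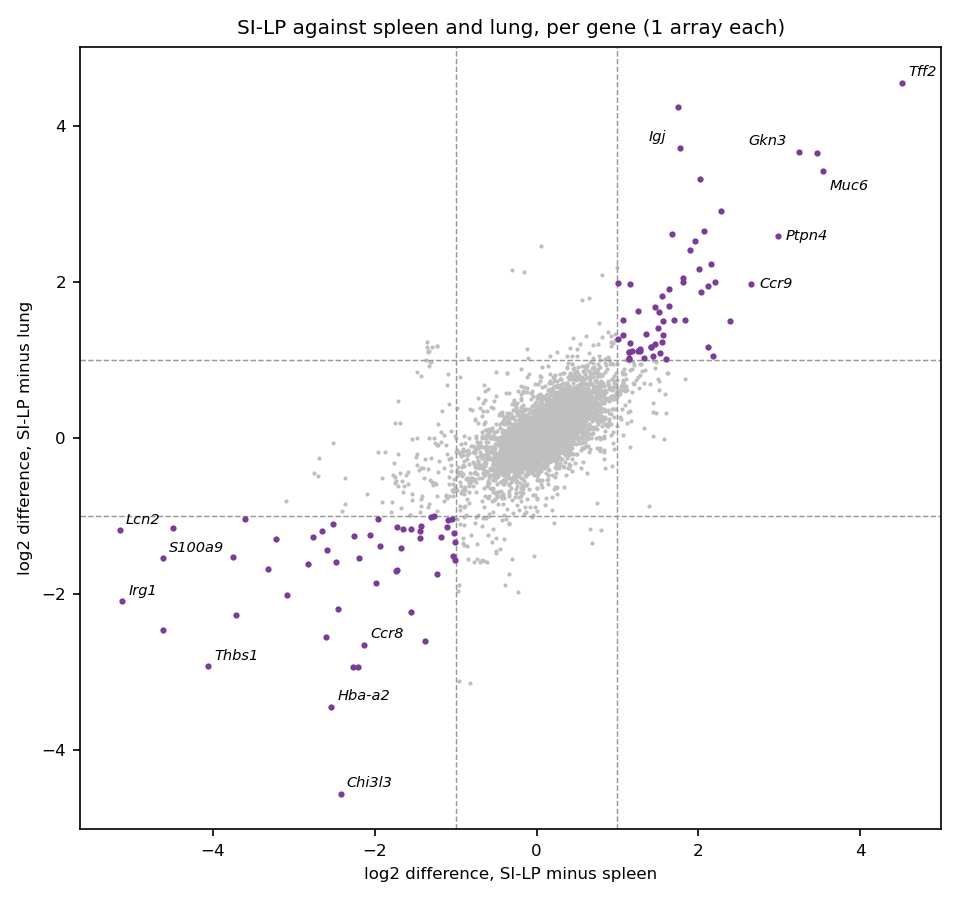
Log2 difference per gene, SI-LP minus spleen (x axis) against SI-LP minus lung (y axis), for the 8780 genes past the filter in both comparisons (1 array per tissue), with dashed lines at 2-fold. The dark points are the 59 genes higher and the 53 genes lower in SI-LP than in both, with Tff2 farthest up in both and Lcn2 and Irg1 farthest down against spleen.

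Antigen receptor segments are part of the counts above and were also counted apart. Immunoglobulin genes with a symbol were higher in SI-LP than in lung for 9 of 12 (none lower, median 2.10), with Igkv10-96 at 4.24. They were higher than in spleen for 5 of 12, by up to 3.46, and 1 was lower (-1.54). In lung, 6 of 10 were lower than in spleen and none higher, Igkv10-96 (-2.49) and Igk (-2.46) most. Of 10 T cell receptor segments, Tcrg-V4, a gamma chain segment, was higher in SI-LP than in spleen (1.64) and lung (1.69) and the others lay within 2-fold.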

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

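The tests in this part were chosen after the results on the named immunoglobulin genes were seen. Probe sets without a gene symbol enter no comparison of the report. By their positions on GRCm38, 16 of them lie in the immunoglobulin kappa locus (chromosome 6, 67555636 to 70726754) and 32 in the heavy chain locus (chromosome 12, 113256204 to 116009954). They were singled out because a signal appeared there in data that no comparison used. In the kappa locus 9 were bright on some array. Of these, 5 were at least 2-fold higher in SI-LP than in lung (median 1.19, 0 lower) and 2 were at least 2-fold lower in lung than in spleen (median -0.37). In the heavy chain locus 16 were bright, 8 were at least 2-fold higher in SI-LP than in lung (median 1.29, 0 lower), and 10 were at least 2-fold lower in lung than in spleen (median -1.28). Between SI-LP and spleen, 2 were higher and 0 lower in the kappa locus, and 4 higher and 4 lower in the heavy chain locus. These values have no replicate, and the design has no control sample without immunoglobulin transcripts.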

How the results depend on the processing

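The alternatives without Il1rn, without Ccl3 and Ccl5 and, for the counts in single comparisons, without members of the lists of other cell types and receptor segments were chosen after seeing the data. All others were planned, the last also for the counts of SI-LP against both. Of 838 list medians computed under other settings, 662 stayed within the spread of random lists, 171 moved by more, and 5 of lists outside the random range turned their sign. Among the others, 30 values of lists within that range had the other sign too. Of 3241 values of single named genes 3235 stayed close and 6 moved. Scaling the arrays in other ways shifted the median of all genes by at most 0.02 and turned the sign only of list medians of at most 0.15, none outside the random range. What limits all values is the lack of replicates, and for dim genes the signal over background, and genes below the arrays' medians on both arrays were not counted.

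With a size limit of 1.5-fold or 3-fold in place of 2-fold, the counts of higher genes were 547 and 34 for SI-LP over spleen, 420 and 36 for SI-LP over lung and 219 and 14 for lung over spleen. The counts of lower genes were 441 and 75, 285 and 37, and 310 and 50. Genes higher in SI-LP than in both numbered 254 and 23, and genes lower than in both 150 and 18. These follow from the limit itself. Without members of the lists of other cell types and receptor segments the counts were 119 higher and 170 lower (SI-LP over spleen), 90 and 105 (SI-LP over lung), 42 and 111 (lung over spleen) and 49 and 49 for SI-LP against both. This does not remove all RNA of other cells. Genes outside those lists stayed in, among them Defa23 on the higher side and Lcn2 and Hba-a2 on the lower side for SI-LP against both. With dim genes counted, the correlation of the SI-LP differences was 0.64.

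The mean in place of the median gave -0.019, 0.16 and -0.18 for the pathogenic signature (SI-LP over spleen, SI-LP over lung, lung over spleen), and -0.58 (SI-LP over spleen) and 0.013 (lung over spleen) for the non-pathogenic one. It turned the intestinal epithelial list to -0.11 against spleen and the NK and innate lymphoid list to 0.26 against lung, since a mean follows single large members such as Olfm4 and Kit. Against random lists not matched on expression the pathogenic median was at percentile 99.69 for spleen and 99.70 for lung, where the brightness of the list's genes is left out. Over all lists and comparisons, 56 medians lay outside the range both ways, 11 only without matching and 3 only with it. The 3 were intestinal epithelial markers (SI-LP over spleen, percentile 87.81), plasma cell markers (SI-LP over lung, 87.73) and cytotoxic genes (lung over spleen, 4.58). After the lowess correction the pathogenic medians against spleen and lung were 0.26 and 0.25 and lay above the random range (percentiles 99.48 and 99.47), as did inhibitory receptors against spleen (99.44), while glycolysis genes against lung lay below it (0.88). The Th17 lineage median was -0.09 for lung over spleen and no longer below it (percentile 4.45). These ranges after the correction were computed after the data were seen, and 19, 22 and 17 of the lists lay outside both ways. A stricter filter on dim genes gave 0.56 for the pathogenic median and 1.24 for the gap between the signatures against lung, and turned the inflammatory homing receptors against spleen to 0.0051. With no filter the non-pathogenic median was -0.094 and the gap 0.36 against lung, and between lung and spleen the follicular helper list turned to -0.013 and the residency list to 0.016. The larger shrinkages of the Paneth cell, neutrophil and chemokine medians with no filter are given above. Other medians outside the random range that shrank with no filter included xenobiotic response genes (0.019 for SI-LP over lung, -0.019 for lung over spleen), dendritic cell markers (-0.12 for SI-LP over spleen, -0.045 for lung over spleen), NK and innate lymphoid markers (-0.11 for SI-LP over lung), erythroid and platelet markers (-0.15 for SI-LP over spleen), plasma cell markers (0.00 for SI-LP over lung and for lung over spleen) and intestinal epithelial markers (0.00 for SI-LP over spleen). Under the stricter filter recirculation genes were at -0.045, cytotoxic genes at -0.89, regulatory T cell genes at -0.43 and macrophage markers at -0.86 for SI-LP over lung, and dendritic cell markers at -0.99, tissue residency genes at -0.46, recirculation genes at -0.16 and regulatory T cell genes at 0.27 for lung over spleen. Leaving out Il1rn gave gaps of 0.45 (SI-LP over lung) and 0.011 (lung over spleen), and leaving out Ccl3 and Ccl5 gave 1.24 (SI-LP over lung). Where no cause is given, the cause was not tested.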

Other observations

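The tests of the 3 patterns below were chosen after the patterns were seen, except those on the lists of other neutrophil genes and of mucous gland genes, whose genes and bounds were written before their values were looked at. Genes in the first paragraphs were picked after their values were seen. Replication-dependent histone genes differed together: 35 of 37 measured Hist genes lay below 0 for SI-LP over lung, 12 of them at least 2-fold lower, with a median of -0.78. Hist1h2ab was at -1.64 and Hist1h2bf at -1.57. Against spleen 35 of 35 lay below 0 with a median of -0.48, and for lung over spleen the median was 0.42. Quantile normalization gave -1.01 and -0.59 and the lowess correction -1.08 and -0.63 for SI-LP over lung and over spleen. These genes are near-identical copies, so single members are uncertain. The cell cycle list showed a median of -0.20 against lung and 0.00 against spleen.

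Several genes on none of the lists set SI-LP apart from both other tissues. The neuropeptide-processing enzyme Cpe was at 6.41 in SI-LP, 4.59 in spleen and 4.41 in lung, and the phosphodiesterase Pde5a at 6.38, 4.82 and 4.88. With log2 differences against spleen and lung, others were the serpin Serpinb1a (1.64 and 1.90) and the incretin receptor Glp1r (1.70 and 1.51). Other genes were shared by SI-LP and lung against spleen: Nt5e, the ecto-nucleotidase CD73, was at 8.05 in lung and 8.04 in SI-LP but 6.46 in spleen, and the proton-sensing receptor Gpr65 at 9.66, 9.98 and 8.38. A further group was highest in lung: Tnfrsf8 (1.49 over spleen, and SI-LP at -1.52 against lung), Rgs16 (10.4, against 9.18 in spleen and 8.88 in SI-LP), S100a4 (6.37, 5.44 and 4.48), Ly6a (6.83, 5.84 and 4.87) and Irf8 (7.52, 6.84 and 5.29). H60a and H60b, ligands of the NKG2D receptor, were lowest in lung: H60a was at 6.23 in lung, 7.37 in spleen and 8.02 in SI-LP, and H60b at 3.53, 4.75 and 5.30.

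Multicopy genes of the Y chromosome with predicted names differed between the arrays: 10 of 10 were at least 2-fold lower in SI-LP than in spleen (median -1.34) and in lung than in spleen (median -2.34), and 4 were at least 2-fold higher in SI-LP than in lung (median 0.99). The single-copy genes Ddx3y (7.69 in spleen, 6.84 in lung, 7.94 in SI-LP) and Eif2s3y (5.49, 4.64 and 5.56) were lowest in lung too. For SI-LP over spleen they were at 0.25 and 0.06, where the multicopy genes were lower. Kdm5d, another single-copy gene, was dim on all 3 arrays. The number of mice per array is not given, and a difference between their mice, sex included, cannot be separated from the tissue.

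Il1rn, Ccl3, Cxcl2 and Osm were lower in SI-LP than in spleen by a median of -2.56, and by -1.26 than in lung. RNA of neutrophils or inflammatory monocytes on the spleen array could account for this, since S100a9 stood at 9.45 there, against 6.37 in lung and 4.83 in SI-LP, although the CD45, TCRβ and CD4 gate would remove such cells. The list of other neutrophil and monocyte genes, none of them on the neutrophil list, had a median of -0.66 over 7 measured members of 14, 2 of them at least 2-fold lower, which fell between the bounds set for and against it. In it Il1r2 (0.01) and Lilrb4 (0.06) were bright on all 3 arrays (10.1 and 10.3 in spleen) and Ltf was at -1.48. Of its 10 named members, Trem1 (-1.60), Mmp8 (-1.38) and Trem3 (-0.75) were dim on both arrays and left out of the median. A lower level in the SI-LP Th17 cells themselves would give a like difference against lung only if lung and spleen Th17 cells were alike. Whether they were is not known, so the ratio of the difference against lung to that against spleen, 0.49, does not decide this. The explanations cannot be told apart and may act together.

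Tff2, Muc6 and Gkn3, secreted products of gastric-type mucous cells, were 9.47-fold to 23.0-fold higher in SI-LP than in spleen, on a sort that should hold only T cells. They were dim in spleen, so these folds are not exact. The values argue against enterocyte RNA: over all 18 named intestinal epithelial genes the median was 0.00 against spleen, 13 lay below the SI-LP array's median, and the largest rise was 0.34 (0.53 against lung). Of 13 named mucous and Brunner's gland genes, 0 were at least 2-fold higher in SI-LP than in both other tissues. Of them 6 were dim. Among the 7 bright ones Spdef rose most (0.11 against spleen, 0.07 against lung). The bound set beforehand took such a result to count against RNA of such cells. The list was not ranked by abundance, so members that such cells express weakly may not show, and the result cannot decide this. That limit was weighed only after the result was seen. The secretory gene Agr2, weighed after its values were seen (1.51 against spleen, 1.41 against lung) and the Paneth genes Defa24 and Lyz1 were higher too. RNA of such cells and a tissue difference in the Th17 cells themselves both stay open, and the latter was not tested.

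Th17 lineage genes had medians of 0.59 and 0.74 in SI-LP over spleen and lung. A higher share of T cells in the SI-LP sample would raise pan T cell genes alike, but their medians were -0.03 and 0.08 on these arrays. Bootstrap intervals over 10 genes ran from -0.36 to 0.20 and from -0.24 to 0.35, below both lineage medians. These intervals resample genes that vary together on single arrays. They leave out the error of sorting, preparation and array, so they cannot exclude such a difference in share. A higher share of IL-17-producing cells among the sorted cells stays possible. The median of the 11 other lineage genes was 0.78 of that of Il17a and Il17f against spleen and 1.09 of it against lung. All these genes are from the list whose rise was already seen, so the ratio is no support for this explanation. The gate on the IL-17 reporter would limit such a difference in share. A higher level per cell in SI-LP would give the same values and stays open. The brightness trend between the arrays can account for part of the values, since the medians of the Th17 lineage list were 0.38 and 0.56 once it was removed by lowess, still above the random range (percentile 99.96 against spleen, and no random list higher against lung).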
